A study of Homo sapiens with 8 samples.

How the data were processed

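RNA was sequenced from PC3 and LNCaP prostate cancer cells grown with a PRMT5 inhibitor (named only PRMT5i in the labels) or with the solvent DMSO. Per the labels' protocols, cells were kept in RPMI1640 medium with 7% serum and treated at 4 µM for 4 days, and total RNA was extracted on RNeasy columns. Libraries were made from 1 µg of total RNA with the Illumina TruSeq Stranded Total RNA kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, STAR 2.5.2, DESeq2 1.18.1 and the genome build GRCh38.p7. The gene annotation, the counting tool and whether counting used the strand are not given in the sources used here. The labels gave 4 groups of 2 libraries each, and all 8 table columns were matched to a library through its description.

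The authors deposited a table of 58037 genes by 8 libraries, whose values are a signal per gene: read counts that the authors divided by a DESeq2 size factor per library, per the file's name and the submitters' processing notes. In every column, 100% of the values were whole multiples of the column's smallest positive value within a tolerance of 0.001, so that whole reads could be recovered by dividing by that step. The reciprocal of the step ran from 0.7816 to 1.4713, and DESeq2 size factors recomputed from the recovered reads differed from it by at most 3.38e-09 percent. The recovered reads summed to between 12020049 and 21597120 per library. At these depths a gene with few reads is poorly measured, and the limits given for groups without a read (3 reads per library) cover counting error only. Identifiers were matched to GENCODE release 29 (GRCh38), which named 57433 of the 58037 genes. Coordinates are 1-based and come from that annotation. The 45 identifiers for the Y copy of the pseudoautosomal regions held 0 reads.

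The main test was limma 3.58.1 with a mean-variance trend (R 4.3.3) on log2(normalized value + 1), with all 8 libraries in a single fit of 4 group means. The fit had 4 residual degrees of freedom and 6.79 prior degrees of freedom. Genes with a value of at least 10 in at least 2 libraries were tested, which left 19114 genes. Log2 changes are on the log2(value + 1) scale, which understates the change of low genes. Tests were two-sided, with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. A gene is said to rise or fall only where it passed that threshold. The contrasts were inhibitor against control in PC3 and in LNCaP, the difference of these responses (LNCaP minus PC3), and the LNCaP controls against the PC3 controls. Calls made in both lines were compared with the overlap of independent lists. The within-line comparisons share no library, but both use the fit's common estimate of each gene's spread. Values are mean ± SD of the 2 libraries of a group, and log2 changes are given ± SE from the fit.

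Before the data were examined, 28 gene lists with 649 entries were fixed, together with the tests, the alternatives and the rule for naming genes. All entries were matched, 2 of them through an older symbol. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, again with the correlation estimated from the libraries, and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. The estimated correlation rests on 4 residual degrees of freedom, which leaves that version imprecise and of little power. A failure there is not evidence that a list stayed unchanged. The preset value ignores higher correlations, such as the 0.325 estimated for the mitotic list, so its p-values can be too small. The rule named the 10 largest rises and the 10 largest falls in PC3, in LNCaP and in the difference. These were taken from called genes that had a symbol and a mean of at least 100 in the higher group. Within a line both treated libraries also had to lie beyond both controls. It also named up to 4 called members of each list with the largest change per line, the members of the line-marker lists for the control comparison, and PRMT5, WDR77, CLNS1A, AR, KLK3, TP53, CDKN1A, MDM2, MDM4, CCND1 and MYC in any case. It gave 240 genes. The text names a part of them, chosen after their values were seen.

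The alternatives were a pseudocount of 0.5 or 8, no filter or a filter at 50, only the 4 libraries compared, upper-quartile scaling, quantile normalization, robust empirical Bayes, an added minimum log2 change of 1, the replicate number as a block, and leaving out each library in turn. On the recovered reads, edgeR 4.0.16 (quasi-likelihood test with TMM) and DESeq2 1.42.0 (Wald test) were run. A scaling to the library total without the 7SL and 7SK RNAs and the mitochondrial genome was added after the data had been seen. For gene lists the added minimum log2 change has no equivalent and was not run. A sign change where neither value passed the threshold was not counted as a reversal.

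The limma, edgeR, DESeq2, camera and fry steps were run on simulated data with known changes, whose outcome is not given here. Genes were drawn independently, with the same dispersion trend in all groups. The simulation therefore could not test the effect of correlation between genes or of the larger spread between the LNCaP controls. DESeq2 left the adjusted p of 1483 genes in PC3 and 4077 in LNCaP undefined, and these stayed undefined. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

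Replicates of each group were compared with a chi-square over genes with at least 20 reads. It averaged 1.49 per gene for the PC3 controls, 1.18 for treated PC3, 3.99 for the LNCaP controls and 1.35 for treated LNCaP, each with a standard error near 0.011 under pure sampling noise, so the libraries of each pair differed by more than the sampling of reads and were counted as 2. This does not show that they came from separate cultures.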

Results

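Expression was measured by RNA sequencing in PC3 cells, an androgen-receptor-negative line, and in LNCaP cells, an androgen-receptor-positive line, both from prostate cancer. Each line was grown with a PRMT5 inhibitor or with DMSO, with 2 libraries per group and 8 in all. PRMT5 is an arginine methyltransferase that symmetrically dimethylates histones and splicing proteins. The recovered reads in genes numbered 12760221 and 14527043 in the PC3 controls, 13252105 and 12020049 in treated PC3, 14505917 and 21597120 in the LNCaP controls, and 16729943 and 16060417 in treated LNCaP. The 7SL and 7SK RNAs took 4.72% and 4.61% of the reads in the PC3 controls and 7.35% and 7.17% in treated PC3. In LNCaP they took 1.84% and 1.97% in the controls and 2.16% and 2.31% with the inhibitor. The mitochondrial genome took between 2.28% and 2.78% in every library. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

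The control libraries were compared to describe the lines before treatment. AR, the androgen receptor, averaged 7944 ± 331 normalized reads in LNCaP controls and 78.9 ± 11.3 in PC3 controls, a difference of 6.64 ± 0.09 on the log2 scale (limma adjusted p = 1.77e-13). KLK3, which encodes prostate-specific antigen, averaged 31875 ± 1524 in LNCaP controls and had no read in either PC3 control, so it was at least 8312-fold higher in LNCaP with a floor of 3 reads per library. The related kallikrein KLK2 averaged 6286 ± 98.5 and was at least 1639-fold higher on the same floor. TMPRSS2, a serine protease gene regulated by androgen, was higher in LNCaP by 3.51 ± 0.07 (adjusted p = 2.04e-12). The intermediate filament gene VIM was lower in LNCaP, with a log2 difference of -3.90 ± 0.07, and so were CD44, CAV1 and ANXA1, which averaged 4552 ± 83.0, 2555 ± 25.04 and 2154 ± 121 in PC3 and 1.27 ± 0.842, 0.807 ± 0.181 and 10.3 ± 2.70 in LNCaP. Of 15 luminal markers written for LNCaP, 13 were higher in LNCaP, and SPDEF and NPY were higher in PC3. Over the scalings and tests tried, the log2 difference ran from -0.56 to -0.37 for SPDEF. For NPY it ran from -4.67 to -1.89, so its size depends on the method. Of the 17 tested basal and mesenchymal markers written for PC3, 16 were higher in PC3, and CAVIN1 was higher in LNCaP. In all, 7644 genes were higher in the LNCaP controls and 7622 in the PC3 controls, out of 19114 tested. The median difference of all genes was 0.01 on the log2 scale, 0.16 under quantile normalization and 0.19 after scaling to the total without 7SL, 7SK and mitochondrial RNA.

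PRMT5 itself (ENSG00000100462.15, chromosome 14, 22920511 to 22929585, minus strand, GRCh38 with GENCODE 29 as for all positions here) did not pass the test in either line. Its mean was 860.3 ± 56.1 in the PC3 controls and 835 ± 33.8 with the inhibitor (log2 change -0.04 ± 0.06, adjusted p = 0.630). In LNCaP it was 1000.1 ± 49.5 and 1036 ± 1.56 (0.05 ± 0.06, adjusted p = 0.627). The genes of its partners WDR77 and CLNS1A did not pass either, with log2 changes of 0.06 ± 0.11 and -0.07 ± 0.06 in PC3 and 0.11 ± 0.11 and -0.02 ± 0.06 in LNCaP. The inhibitor acts on the enzyme, and these values describe messenger RNA only.

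**Figure D1:**
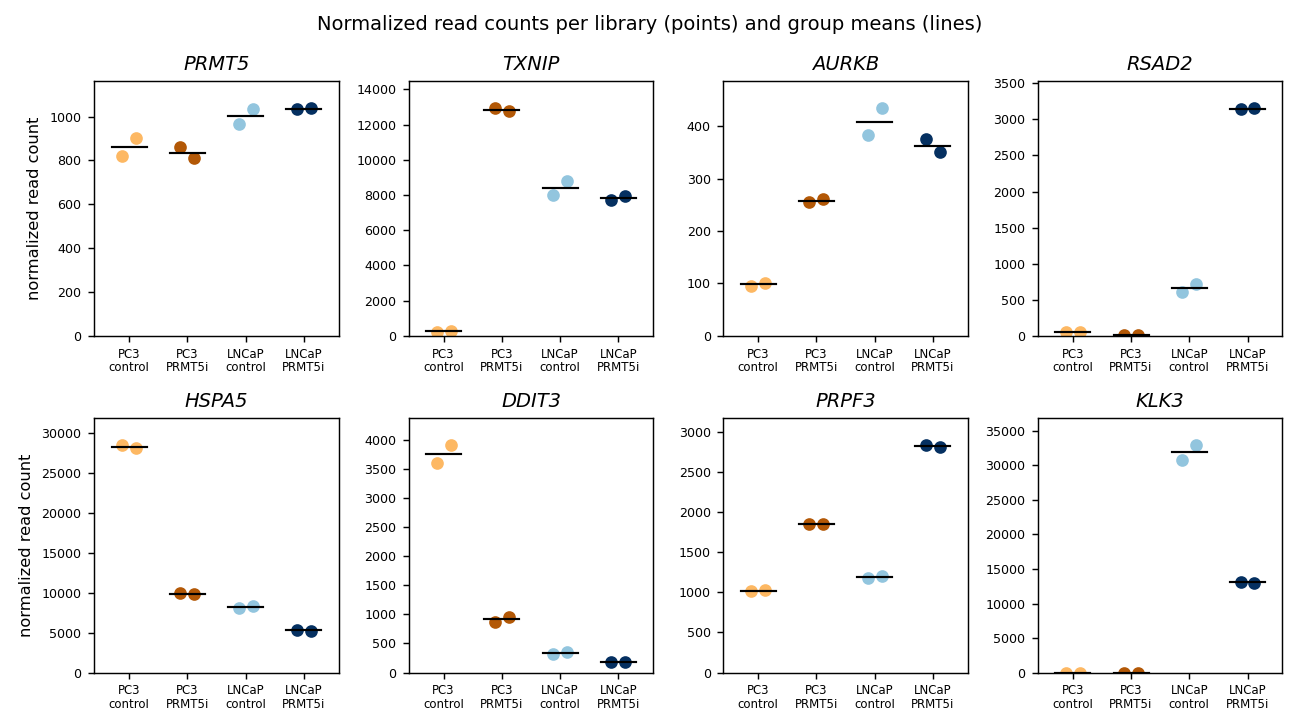
Normalized read counts of 8 genes in each library (points, 2 per group) and group means (lines), with group on the x axis and the count, from 0, on the y axis. PRMT5 averaged 860.3 in the PC3 controls and 1000.1 in the LNCaP controls, TXNIP rose from 262 to 12849 in PC3, and RSAD2 fell in PC3 and rose from 665 to 3146 in LNCaP.

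The response of PC3 cells was the first treatment comparison. The largest rise was in TXNIP (ENSG00000265972.5, chromosome 1, 145992435 to 145996600, minus strand), which encodes a thioredoxin-binding arrestin that restrains glucose uptake. TXNIP went from 262 ± 22.1 to 12849 ± 103 normalized reads, a log2 change of 5.61 ± 0.07 (48.9-fold, limma adjusted p = 2.07e-12). ARRDC4, a gene of the same arrestin family (chromosome 15, 97960698 to 97973838), rose 8.37-fold, from 58.7 ± 3.76 to 499 ± 34.7. Other rises included CPA4 (2.70 ± 0.48), KCND1 (2.60 ± 0.29), AOC3 (2.38 ± 0.22), RBP4 (2.32 ± 0.21) and the kinetochore gene ZWINT (2.20 ± 0.05). The largest fall was in the calcium channel gene CACNA1S (chromosome 1, 201039512 to 201112566), from 279.8 ± 7.03 to 12.2 ± 1.01, a log2 change of -4.41 ± 0.25 (adjusted p = 2.58e-07). FCGBP fell from 2814 ± 80.1 to 162 ± 2.65, and MUC2, a secreted mucin gene, from 379 ± 5.01 to 34.1 ± 13.3. CDH15, FCGR2A, LINC01547, IDO1 and PGGHG fell by 3.33 ± 0.17, 3.19 ± 0.38, 3.11 ± 0.07, 2.72 ± 0.19 and 2.72 ± 0.10 on the log2 scale.

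Cell division genes rose in PC3. Of 40 genes of G2 and mitosis, 39 rose and 0 fell, also when adjusted over the list alone, with a mean log2 change of 0.94 (camera adjusted p = 8.43e-26, adjusted p = 0.254 with an estimated correlation). The checkpoint kinase gene TTK rose by 1.40 ± 0.07, the kinase gene AURKB by 1.39 ± 0.10 and the checkpoint gene MAD2L1 by 1.37 ± 0.07. Of 42 genes of DNA replication and E2F targets, 35 rose and 2 fell, also when adjusted over the list alone (mean 0.63, camera adjusted p = 3.69e-13, adjusted p = 0.352 with an estimated correlation). E2F1, a transcription factor of S-phase entry, went from 171 ± 15.1 to 537 ± 52.6, and the replication gene MCM10 from 54.5 ± 4.28 to 168 ± 9.14. Of 30 genes of double-strand break repair, 18 rose and 3 fell (18 and 4 adjusted over the list alone, mean 0.38, camera adjusted p = 1.36e-04, adjusted p = 0.296 with an estimated correlation), with the nuclease gene EXO1 at 1.37 ± 0.11 and the helicase gene BLM at 1.36 ± 0.11. Of 40 spliceosome and hnRNP genes, 25 rose and 5 fell (27 and 5 adjusted over the list alone, mean 0.29, camera adjusted p = 2.86e-06, adjusted p = 0.302 with an estimated correlation), including LUC7L (0.97 ± 0.06), PRPF3 (0.86 ± 0.05), SRSF2 (0.67 ± 0.06) and PRPF8 (0.61 ± 0.05). Among cell cycle regulators, E2F8 rose by 1.92 ± 0.15 and CCND1, the cyclin D1 gene, by 0.38 ± 0.05. CDKN2B, CDKN1A and MYC fell by 1.51 ± 0.07, 0.67 ± 0.06 and 0.52 ± 0.06. That list of 22 tested genes had 7 rises and 10 falls (7 and 11 adjusted over the list alone) and did not pass camera (adjusted p = 0.294), except on the DESeq2 values (adjusted p = 0.0498).

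Of 30 type I interferon response genes, 0 rose and 28 fell in PC3, also when adjusted over the list alone, with a mean log2 change of -1.15 (camera adjusted p = 2.47e-14, adjusted p = 0.254 with an estimated correlation). The antiviral gene OAS2 went from 343 ± 0.366 to 64.4 ± 1.21, RSAD2 from 49.95 ± 3.76 to 11.7 ± 3.30, and IFIT1 from 228 ± 20.5 to 85.2 ± 1.02. Of 24 NF-kB and inflammatory genes, 0 rose and 19 fell, also when adjusted over the list alone (mean -0.91, camera adjusted p = 1.97e-07, adjusted p = 0.218 with an estimated correlation). The adhesion gene ICAM1 fell from 5777 ± 244 to 1569 ± 37.4, and the chemokine genes CXCL2 and CCL20 fell by 2.20 ± 0.29 and 1.70 ± 0.19.

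Of 18 endoplasmic reticulum chaperone genes, 17 fell and 0 rose in PC3, also when adjusted over the list alone (mean -1.13, camera adjusted p = 2.47e-14, adjusted p = 0.355 with an estimated correlation). HSPA5, the BiP gene (chromosome 9, 125234853 to 125241330), went from 28239 ± 287 to 9853 ± 48.4, and DNAJB9, HERPUD1 and MANF fell by 1.93 ± 0.08, 1.93 ± 0.06 and 1.78 ± 0.05. Of 24 genes of the integrated stress response, 18 fell and 3 rose, also when adjusted over the list alone (mean -0.55, camera adjusted p = 3.68e-06, adjusted p = 0.455 with an estimated correlation). PCK2 and DDIT3, which encodes CHOP, fell by 2.08 ± 0.09 and 2.04 ± 0.08, and the glutathione-degrading gene CHAC1 fell by 1.16 ± 0.13. SLC7A5, an amino acid transporter gene, was among the rises (0.53 ± 0.11). Of 24 cholesterol synthesis genes, 18 fell and 1 rose (19 and 1 adjusted over the list alone, mean -0.40, camera adjusted p = 4.97e-05, adjusted p = 0.455 with an estimated correlation), with TM7SF2 at -1.55 ± 0.06 and STARD4 going from 1430.2 ± 8.79 to 715 ± 24.4.

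Over all 19114 genes tested, limma called 8642 in PC3, of which 3825 rose and 4817 fell, and 2305 changed at least 2-fold (1094 up, 1211 down). The share of rises among the calls was 44.3%, and 59.7% after scaling to the total without 7SL, 7SK and mitochondrial RNA, a choice made after the data were seen. The 7SL and 7SK RNAs went from 4.72% and 4.61% of the reads in the controls to 7.35% and 7.17% in these treated libraries. That scaling moved the median change of all genes from -0.02 to 0.08 on the log2 scale. Of 7 fibroblast markers tested, LUM, ACTA2 and COL3A1 rose, by 3.19, 1.69 and 1.10 on the log2 scale, from means of 6.49, 3.50 and 9.62. With only the 4 PC3 libraries in the fit ACTA2 and COL3A1 lost their calls. Without PC3 control replicate 1 the value was 0.91 for ACTA2 and COL3A1 lost its call (adjusted p = 0.0699), as it did without treated replicate 2 (0.62, adjusted p = 0.118). No list named for PC3 passed the test with an estimated correlation.

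In LNCaP, 22 of 30 interferon genes rose, and 36 of 40 genes of mitosis, 22 of 27 genes of glycolysis and hypoxia and 15 of 28 androgen receptor targets fell. None of these lists passed with an estimated correlation (adjusted p from 0.330 to 0.357). Falls of single genes included the chemokine gene CCL20 (chromosome 2, 227805739 to 227817564), from 166 ± 37.0 to 27.5 ± 3.20, a log2 change of -2.53 ± 0.19 (limma adjusted p = 1.05e-05). ADAM7, SLITRK6, KRT19, SLC22A3, DIO3 and SLC7A11 fell by 2.39 ± 0.48, 2.07 ± 0.10, 1.90 ± 0.07, 1.79 ± 0.27, 1.65 ± 0.14 and 1.57 ± 0.05. Rises included CPHL1P, a pseudogene (57.4 ± 11.1 to 298 ± 23.7, 2.37 ± 0.25), and RSAD2 (ENSG00000134321.11, chromosome 2, 6865806 to 6898239, plus strand), an antiviral gene that went from 665 ± 81.0 to 3146 ± 9.94 (2.25 ± 0.16, 4.74-fold, adjusted p = 7.24e-06). The chemokine genes CXCL11, CCL5 and CXCL10 rose by 2.02 ± 0.27, 1.95 ± 0.37 and 1.73 ± 0.42.

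Interferon genes rose in LNCaP: of 30, 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a mean log2 change of 0.97 (camera adjusted p = 1.09e-22, adjusted p = 0.330 with an estimated correlation). IFIT1 went from 1851 ± 110.1 to 6656 ± 38.4, IFIT3 from 1109.5 ± 145 to 3614 ± 57.0, and OAS2 from 146 ± 1.31 to 351 ± 23.2. IDO1, an interferon-induced tryptophan-degrading enzyme gene, rose from 28.4 ± 0.795 to 82.3 ± 0.471. Of 24 NF-kB and inflammatory genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone, mean 0.09, camera adjusted p = 0.00514, adjusted p = 0.330 with an estimated correlation), with LIF at 1.05 ± 0.12 and BIRC3 at 0.70 ± 0.05. Of 29 p53 targets, 9 rose and 2 fell, also when adjusted over the list alone (mean 0.07, camera adjusted p = 0.0316, adjusted p = 0.612 with an estimated correlation). PLK2, FAS and the cell cycle inhibitor gene CDKN1A rose by 0.67 ± 0.06, 0.49 ± 0.13 and 0.32 ± 0.06, and FDXR fell by 0.78 ± 0.09. TP53 rose by 0.27 ± 0.08. In PC3 TP53 fell, with a log2 change from -0.37 to -0.24 over the scalings and tests tried. That call was lost with edgeR, with DESeq2 and with only the 4 PC3 libraries in the fit. In LNCaP MDM2 and MDM4 did not pass the test (0.05 ± 0.06 and 0.12 ± 0.06). Both were called as rising after upper-quartile scaling, quantile normalization and scaling to the total without 7SL, 7SK and mitochondrial RNA (0.14 to 0.18 for MDM2 and 0.20 to 0.21 for MDM4, adjusted p from 0.00956 to 0.0407), and MDM4 also with edgeR (adjusted p = 0.0278). PMAIP1, which encodes the apoptosis factor NOXA, rose from 246 ± 7.39 to 523 ± 11.2, within a list of 24 apoptosis regulators that had 4 rises and 4 falls. CDKN2B rose by 0.85 ± 0.07 and CCND1 fell by 0.30 ± 0.05.

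KLK3 (chromosome 19, 50854915 to 50860764) went in LNCaP from 31875 ± 1524 to 13080.0 ± 84.6, a log2 change of -1.28 ± 0.11 (adjusted p = 2.13e-05). AR did not pass the test in LNCaP (7944 ± 331 and 7182 ± 71.9, log2 change -0.145, limma adjusted p = 0.296), but was called as falling with edgeR (-0.12, adjusted p = 0.0327) and DESeq2 (-0.13, adjusted p = 0.0358). In PC3 AR rose by 0.54 ± 0.09, from 78.9 ± 11.3 to 114.9 ± 9.40, a call that was lost with only the 4 PC3 libraries in the fit. Of 28 androgen receptor targets tested, 15 fell and 0 rose, also when adjusted over the list alone (mean -0.38, camera adjusted p = 1.24e-07, adjusted p = 0.357 with an estimated correlation), with HPGD, NDRG1 and KLK2 falling by 1.53 ± 0.11, 0.76 ± 0.07 and 0.69 ± 0.15. Of the 15 luminal markers, which share KLK3, KLK2 and other genes with that list, 7 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.00112, adjusted p = 0.357 with an estimated correlation). Of 40 genes of G2 and mitosis, 36 fell and 0 rose (37 and 0 adjusted over the list alone, mean -0.46, camera adjusted p = 1.38e-19, adjusted p = 0.330 with an estimated correlation). TOP2A, KIF20A and CDC20 fell by 0.95 ± 0.05, 0.83 ± 0.08 and 0.74 ± 0.06. Of 42 replication genes and E2F targets, 24 fell and 0 rose (27 and 0 adjusted over the list alone, mean -0.34, camera adjusted p = 1.22e-09, adjusted p = 0.357 with an estimated correlation), led by the ribonucleotide reductase gene RRM2 (-1.26 ± 0.06) and MCM4 (-0.87 ± 0.06). Of 23 replication-dependent histone genes, 18 fell and 0 rose (20 and 0 adjusted over the list alone, mean -0.59, camera adjusted p = 5.50e-13, adjusted p = 0.330 with an estimated correlation), among them HIST1H3A (-1.28 ± 0.09), HIST1H2AG (-0.90 ± 0.07) and HIST1H1C (-0.75 ± 0.06).

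Of 27 glycolysis and hypoxia genes, 22 fell in LNCaP and 0 rose (24 and 0 adjusted over the list alone, mean -0.51, camera adjusted p = 7.94e-16, adjusted p = 0.330 with an estimated correlation). PFKFB4, PDK1 and BNIP3 fell by 1.11 ± 0.06, 1.04 ± 0.08 and 0.71 ± 0.05. Of 24 integrated stress response genes, 17 fell and 3 rose, also when adjusted over the list alone (mean -0.54, camera adjusted p = 1.22e-09, adjusted p = 0.342 with an estimated correlation), with CHAC1, SLC7A5 and PCK2 falling by 1.69 ± 0.13, 1.33 ± 0.11 and 1.17 ± 0.09. Of 18 endoplasmic reticulum chaperone genes, 10 fell and 1 rose (13 and 1 adjusted over the list alone, mean -0.26, camera adjusted p = 3.92e-06, adjusted p = 0.517 with an estimated correlation). Spliceosome and hnRNP genes had 10 rises and 4 falls among 40 (11 and 5 adjusted over the list alone, mean 0.10, camera adjusted p = 0.0316, adjusted p = 0.517 with an estimated correlation), led by PRPF3 (1.24 ± 0.05), LUC7L (0.84 ± 0.06) and PRPF8 (0.51 ± 0.05). Cytosolic ribosomal protein genes (4 fell and 0 rose of 40, 3 and 0 adjusted over the list alone, camera adjusted p = 0.0175) had a mean of -0.10 that turned to 0.04 under quantile normalization, and adjusted p was 0.777 with an estimated correlation. Mitochondrially encoded mRNAs had 3 rises and 0 falls among 13, also when adjusted over the list alone (mean 0.09, camera adjusted p = 0.0254, adjusted p = 0.517 with an estimated correlation).

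Over all genes tested, limma called 4340 in LNCaP, of which 1598 rose and 2742 fell, and 555 changed at least 2-fold (391 up, 164 down). The 2 LNCaP controls differed more than the other pairs (chi-square of 3.99 per gene). The single fit shares a gene's spread among all 4 groups, so the LNCaP standard errors and p-values can understate that difference. With only the 4 LNCaP libraries in the fit 997 genes were called, and 2149 and 2197 without treated replicate 1 and treated replicate 2. Without control replicate 1, 1366 rose and 3345 fell, and without control replicate 2, 1453 rose and 1715 fell. The share of rises was 36.8%, against 57.0% after upper-quartile scaling, 49.6% after quantile normalization and 58.3% after scaling to the total without 7SL, 7SK and mitochondrial RNA. With only those 4 libraries the calls of TP53, FAS, CDKN1A, CCND1, CDKN2B, LIF, SLC7A5 and the spliceosome and ribosomal protein lists were lost. KLK2 lost its call without any 1 of the LNCaP libraries (adjusted p from 0.0670 to 0.120), and so did CXCL10 (0.0883 to 0.0982), which also lost it with a pseudocount of 0.5 (0.0741) or no filter (0.0621). ADAM7 lost it without control replicate 2 (adjusted p = 0.0545) or treated replicate 1 (0.0558), and FAS without control replicate 1 (0.0996) or treated replicate 1 (0.0938) or 2 (0.131). TP53 lost it without control replicate 1 (log2 change 0.17, adjusted p = 0.210), treated replicate 1 (0.203) or 2 (0.161), or PC3 control replicate 1 (0.0508) or 2 (0.0507), and with no filter (0.112). Of the lists, the p53 targets lost their call without control replicate 1 (mean 0.02, adjusted p = 0.140) or treated replicate 1 (0.0843), and had a mean of 0.12 without control replicate 2. The spliceosome genes lost theirs without control replicate 1 (adjusted p = 0.140) or treated replicate 2 (0.0592), and the mitochondrially encoded mRNAs without control replicate 2 (mean 0.05, adjusted p = 0.222) or treated replicate 1 (0.0723). The ribosomal protein genes lost theirs without control replicate 2 (mean -0.02, adjusted p = 0.603) or treated replicate 1 (0.105), and had a mean of -0.18 without control replicate 1. They also lost it with a filter at 50 (0.118), upper-quartile scaling (0.386) and scaling to the total without 7SL, 7SK and mitochondrial RNA (0.459). The NF-kB list kept its call, with a mean of 0.04 without treated replicate 1 and 0.14 without treated replicate 2. None of the 14 lists passed with an estimated correlation (adjusted p from 0.330 to 0.777). The p53 targets, ribosomal protein genes and mitochondrially encoded mRNAs also did not pass fry, which tests whether a list moves one way on balance and does not compare it with other genes.

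The responses of the lines were compared with each other, since the lines differ in androgen receptor status. Their controls differed in 15266 genes, so a difference in response cannot be put down to that status. The test of the difference called 5892 genes, 3046 with the more positive change in LNCaP and 2846 with the more positive change in PC3. This balance depended on the scaling. The counts were 3657 and 2915 with upper-quartile scaling and 3175 and 3452 under quantile normalization. They were 3065 and 3658 after scaling to the total without 7SL, 7SK and mitochondrial RNA. RSAD2 fell in PC3 and rose in LNCaP, a difference of 4.27 ± 0.23 (limma adjusted p = 5.88e-07), and OAS2 and IFIT1 behaved alike (3.66 ± 0.14 and 3.25 ± 0.10). All 40 genes of G2 and mitosis had the more positive change in PC3 by this test, also when adjusted over the list alone, with a mean difference of -1.40 (camera adjusted p = 1.10e-36, adjusted p = 0.135 with an estimated correlation). For the interferon list, 28 of 30 genes had the more positive change in LNCaP (29 adjusted over the list alone, mean 2.12, camera adjusted p = 2.78e-27, adjusted p = 0.124 with an estimated correlation). The integrated stress response list had 18 falls and 3 rises in PC3 and 17 falls and 3 rises in LNCaP (adjusted p = 0.455 and 0.342 with an estimated correlation). Its mean difference was 0.01 (camera adjusted p = 0.919), with 8 genes on each side past the test (9 adjusted over the list alone). DDIT3 and PCK2 fell further in PC3 (differences 1.19 ± 0.11 and 0.91 ± 0.13). For PRPF8, LUC7L and FDXR, which changed the same way in both lines, the difference was -0.10 ± 0.07, -0.13 ± 0.09 and 0.15 ± 0.13, none of which passed the test.

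**Figure D2:**
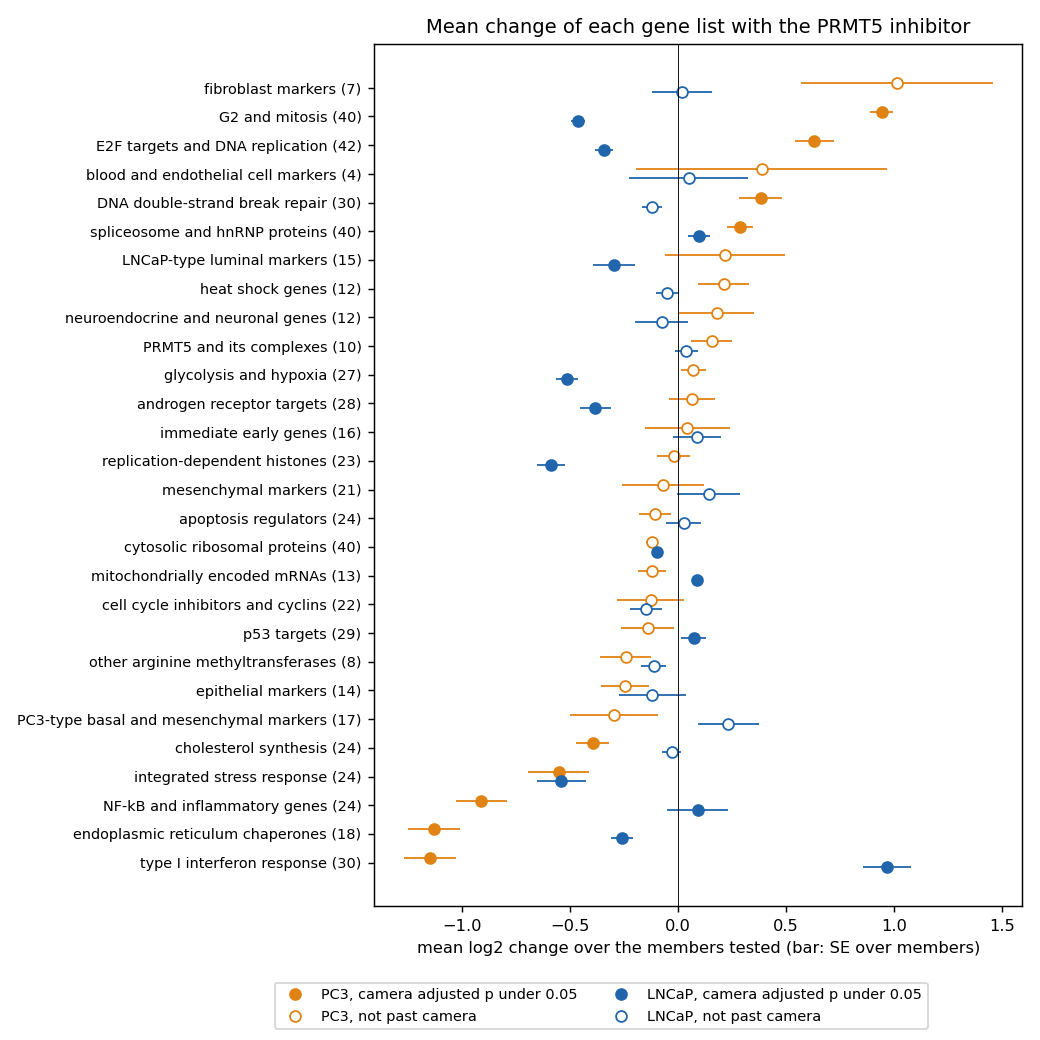
Mean log2 change with the inhibitor over the members tested of each of the 28 gene lists (x axis, members in parentheses), in PC3 and LNCaP, with bars for the SE over members and filled points where camera passed at 0.05. Interferon genes averaged -1.15 in PC3 and 0.97 in LNCaP, and genes of G2 and mitosis 0.94 and -0.46.

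Calls in both lines numbered 2705, of which 1869 (69.1%) had the same direction and 836 the opposite. Both sets of calls came from a single fit that shares each gene's spread between the lines. Genes with a small spread or many reads can thus be called in both without a common response. The counts for independent lists are therefore a reference and not a chance level, and Fisher's exact test treats the genes as independent. Of the shared calls, 583 rose in both lines, where independent lists of these sizes would share 320, and 1286 fell in both, where they would share 691 (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.77e-57 and 2.78e-157). Rises in PC3 that fell in LNCaP numbered 482 (549 for independent lists, adjusted p = 8.74e-04), and falls in PC3 that rose in LNCaP 354 (403, adjusted p = 0.00424). Among genes changed at least 2-fold in both lines the last of these went the other way, with 37 that fell in PC3 and rose in LNCaP against 24.8 for independent lists (adjusted p = 0.0174). At that size 8 rose in PC3 and fell in LNCaP (9.39, adjusted p = 0.865), 64 rose in both (22.4, adjusted p = 5.71e-14) and 29 fell in both (10.4, adjusted p = 8.82e-07). Across the 19114 genes, which are not independent replicates, the log2 changes of the lines had a Pearson r of 0.174 and a Spearman rho of 0.195. The number with the same direction was 437 when each line was fitted alone, and 961 and 957 without treated LNCaP replicate 1 and treated LNCaP replicate 2.

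**Figure D3:**
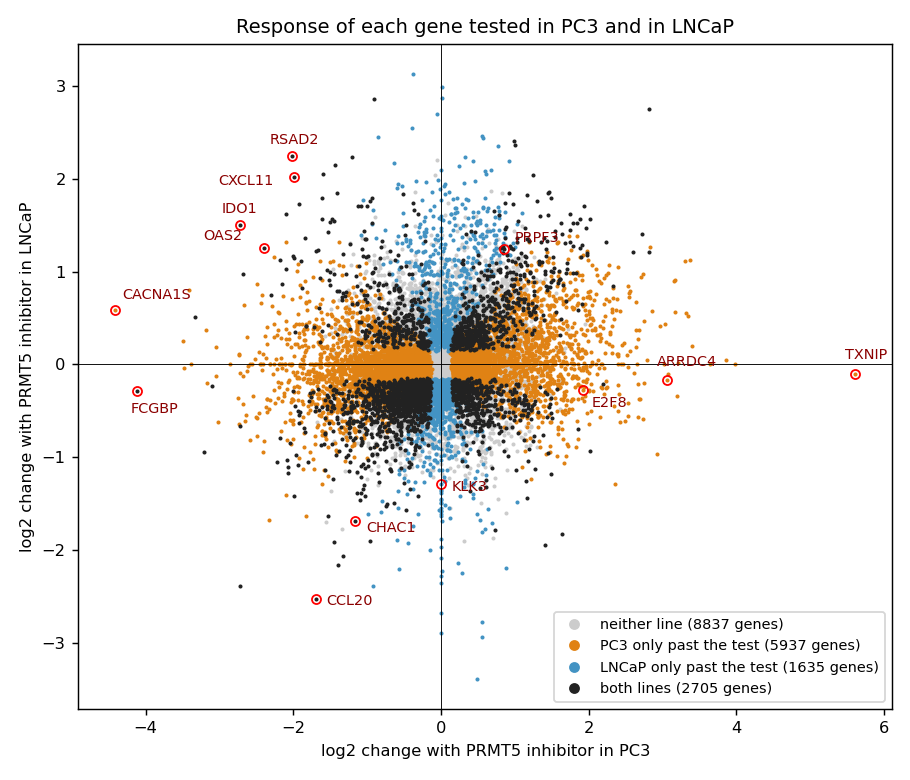
Log2 change with the inhibitor in PC3 (x axis) and LNCaP (y axis) for each of the 19114 genes tested, coloured by the lines in which limma called the gene, with named genes circled in red. TXNIP lies at 5.61 on the PC3 axis and near 0 for LNCaP (-0.10), and RSAD2 at -2.02 and 2.25.

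Some of these genes share sequence with others. Exons of FCGR2A, MDM2, TM7SF2, SRSF2, RRM2, PFKFB4, DDIT3 and WDR77 overlap those of another annotated gene on the same strand. Exons of VIM, CD44, PRMT5, WDR77, TP53, CDKN1A, MDM2, CCND1, IDO1, MAD2L1, DNAJB9, RSAD2, ICAM1, DDIT3, STARD4, PRPF8, SRSF2, E2F8, ADAM7, SLC7A11, KIF20A, PDK1, SLC7A5, FAS and LIF overlap a gene on the opposite strand. Histone genes and FCGR2A have close relatives in the genome, CPHL1P is a pseudogene, and all these values are uncertain to the extent that reads were divided among copies or strands.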

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

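Every result here was picked out because the test of the difference between the responses of LNCaP and PC3 passed at an adjusted p of 0.05. The tests of RNA from the other line, of the scaling, of single control libraries and of overlapping genes were chosen only after the result had been seen. Differences are LNCaP minus PC3 on the log2 scale. The difference itself covered 5892 genes.

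The first pattern is that interferon genes fell in PC3 (mean -1.15) and rose in LNCaP (0.97), a mean difference of 2.12, and did not pass with an estimated correlation (adjusted p = 0.254 in PC3 and 0.330 in LNCaP). RNA of the other line in the treated libraries could not make this pattern at any share for most of these genes. A mixture would need a share below 0 or above all of the RNA for 22 of the 30 in PC3 and 23 in LNCaP. For these the control levels settled the outcome, so the low shares of marker genes add no support. The 48 genes abundant in LNCaP and nearly absent from PC3 gained a median of 0.0145% of their LNCaP level in treated PC3. The 156 abundant in PC3 gained 0.0182% of their PC3 level in treated LNCaP. After a smooth trend of each library with GC content and transcript length was removed, the means were -1.13 and 0.97 (camera adjusted p = 2.31e-14 and 2.53e-22), so that trend was not the whole cause. Those p used the preset correlation, and with the trend removed no estimated one was run. A difference in the state of the cultures stays open, and so does a response that depends on the line. Androgen receptor status is only 1 of the differences between the lines, and its part was not tested.

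The second pattern is that mitotic genes rose in PC3 (mean 0.94) and fell in LNCaP (-0.46), a difference of -1.40. With the GC content and length trend removed, the means were 0.95 and -0.45 (camera adjusted p = 1.31e-24 and 5.08e-19), and before it adjusted p = 0.254 and 0.330 with an estimated correlation. Under the scaling that left least of the change they were 0.96 and -0.37, and without a single LNCaP control library -0.41 or -0.52. None of these accounts for the pattern. The scalings moved the median change of all genes only between -0.02 and 0.08 in PC3 and between -0.03 and 0.05 in LNCaP. They could therefore hardly have removed either mean, and the test of the scaling adds little. Cell density or growth rate at harvest, which the labels do not give, could differ between the groups and stays open, as does a difference between the lines.

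The third pattern is the rise of TXNIP and ARRDC4 in PC3, with differences of -5.71 and -3.23. Reads of overlapping genes are argued against, since 0 annotated genes overlap the exons of either. LNCaP RNA in the treated PC3 libraries would need 155% of the RNA for TXNIP, against the 0.0145% found in LNCaP genes. Both genes are known to respond to glucose, and the medium at harvest may differ between the groups, which the labels do not settle.

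Other lists with a positive difference were endoplasmic reticulum chaperones (mean 0.87), NF-kB and inflammatory genes (1.00), cholesterol synthesis (0.37), PC3-type basal and mesenchymal markers (0.53), p53 targets (0.21) and mitochondrially encoded mRNAs (0.21). Lists with a negative difference were E2F targets and DNA replication (-0.97), glycolysis and hypoxia (-0.58), replication-dependent histones (-0.57), LNCaP-type luminal markers (-0.51), DNA double-strand break repair (-0.50), androgen receptor targets (-0.45), heat shock genes (-0.26) and spliceosome genes (-0.19). With an estimated correlation the adjusted p of the 16 lists ran from 0.124 to 0.543.

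Among interferon and chemokine genes the difference was 4.27 for RSAD2, 4.22 for IDO1, 4.01 for CXCL11, 3.66 for OAS2, 3.65 for CXCL10, 3.25 for IFIT1, 2.84 for IFIT3, 2.53 for CCL5, 2.20 for CXCL2, 2.08 for ICAM1, 1.58 for LIF, 1.01 for BIRC3 and -0.83 for CCL20. CXCL10, CXCL11 and CCL5 had few or no reads in PC3, and CXCL2 none in LNCaP, so their fitted differences depend on the pseudocount. Of the division and replication genes, ZWINT had -2.41, E2F8 -2.20, MCM10 -1.85, E2F1 -1.80, TTK -1.70, AURKB -1.55, BLM -1.54, CDC20 -1.52, MAD2L1 -1.47, EXO1 -1.44, KIF20A -1.39, TOP2A -1.31, RRM2 -1.31, MCM4 -1.20, HIST1H2AG -0.86, HIST1H1C -0.80 and HIST1H3A -0.78. Of the regulators, CDKN2B had 2.36, PMAIP1 1.35, CDKN1A 0.98, TP53 0.64, PLK2 0.58, FAS 0.54, MYC 0.53, MDM4 0.25 and CCND1 -0.69.

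Of the stress, chaperone and metabolic genes, DNAJB9 had 1.801, TM7SF2 1.63, MANF 1.47, HERPUD1 1.29, DDIT3 1.19, PCK2 0.91, HSPA5 0.89, STARD4 0.75, CHAC1 -0.53, PFKFB4 -0.67, BNIP3 -0.93, SLC7A11 -1.09, PDK1 -1.32 and SLC7A5 -1.87. Of the androgen-regulated genes, AR had -0.69, NDRG1 -0.62, KLK2 -0.69, HPGD -0.78 and KLK3 -1.28, where KLK2 and KLK3 had no read in PC3. Of the splicing genes, PRPF3 had 0.39 and SRSF2 -0.51. The remaining named genes were CACNA1S (4.997), CDH15 (3.84), FCGBP (3.82), MUC2 (3.74), FCGR2A (3.56), LINC01547 (2.87), PGGHG (2.63), CPHL1P (1.36), SLITRK6 (-0.74), KRT19 (-0.94), KCND1 (-1.38), RBP4 (-1.75), ACTA2 (-1.98), LUM (-3.53), DIO3 (-1.77), AOC3 (-2.26) and SLC22A3 (-2.52).

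With edgeR and with DESeq2 the differences of KLK2, KLK3, CXCL2, CCL5, LUM, FAS and the luminal markers did not pass, nor did that of CCL20 with DESeq2 or of the PC3-type markers with edgeR. Under quantile normalization the luminal markers, the PC3-type markers and the mitochondrially encoded mRNAs lost the difference, and so did the luminal markers and mitochondrially encoded mRNAs after scaling to the total without 7SL, 7SK and mitochondrial RNA. With a filter at 50 these 3 lists and the heat shock genes lost it. With no filter the differences of CHAC1, CCL20, FAS, ACTA2, KCND1 and MDM4 did not pass (adjusted p from 0.0587 to 0.131). CHAC1 also lost it with a pseudocount of 0.5 (0.0577) or 8 (0.0727) and upper-quartile scaling (0.0509), KLK2 with a pseudocount of 0.5 (0.0663), upper-quartile scaling (0.0506) and the total without 7SL, 7SK and mitochondrial RNA (0.0508), and MDM4 with that total (0.0666). Some calls were also lost when a single library was left out. Such a fit leaves a lone library in a group, so a lost call alone does not show that a value rests on that library. The difference of KLK2 ran from -0.707 to -0.675 without any 1 LNCaP library, against -0.691 with all, while CHAC1 and ACTA2 moved further. The difference was lost for CCL20 without any 1 library except LNCaP control replicate 1 (adjusted p from 0.0522 to 0.133), for CHAC1 without any except treated LNCaP replicate 2 (0.0588 to 0.157, and -0.32 without treated LNCaP replicate 1), and for FAS without any except LNCaP control replicate 2 (0.0591 to 0.145). It was lost for ACTA2 without any except the PC3 controls (0.0583 to 0.0855), and without PC3 control replicate 1 its value was -1.20. For KCND1 it was lost without any except PC3 control replicate 1 and LNCaP control replicate 2 (0.0502 to 0.0877, and -0.94 without LNCaP control replicate 1), and for KLK2 without any 1 of the LNCaP libraries (0.121 to 0.169). For MDM4 it was lost without PC3 control replicate 1 or any 1 treated library (0.0563 to 0.122), and for CPHL1P without treated PC3 replicate 2, LNCaP control replicate 1 or treated LNCaP replicate 1 (0.0545 to 0.0735). The luminal markers lost it without PC3 control replicate 2, treated PC3 replicate 2 (mean -0.29) or either LNCaP control (0.0517 to 0.0781), and the PC3-type markers without treated PC3 replicate 2 (0.0501). The heat shock genes lost it without PC3 control replicate 1 (mean -0.17), treated PC3 replicate 1 or treated LNCaP replicate 1 (0.0568 to 0.111), and the mitochondrially encoded mRNAs without treated PC3 replicate 1, LNCaP control replicate 2 or treated LNCaP replicate 1 (0.0568 to 0.0881).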

How the results depend on the processing

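The scaling to the total without 7SL, 7SK and mitochondrial RNA was chosen after the data had been seen, and the other alternatives before. For PC3 genes changed by the inhibitor, counts stayed within 1.5 times of 8642 under every alternative except the added 2-fold minimum (2305). For LNCaP (4340), the count was 997 with only the 4 libraries compared and 555 with the 2-fold minimum. Leaving out single libraries gave 2149 to 4711 in LNCaP, 6728 to 9145 in PC3, 4179 to 5890 for the difference, 14243 to 15119 for the controls, and 957 to 2172 for genes called in both lines in the same direction. A lone library left in a group was assumed to vary like the other groups. That last count (1869) was 1207 with no filter on low values, 437 with only the 4 libraries compared and 93 with the 2-fold minimum. The 2-fold minimum left 1835 genes for the difference of responses and 9289 for the controls. A minimum change keeps fewer genes by construction. The cause of the lower counts with only the 4 libraries compared, without single libraries and without the filter was not tested.

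The replicate number as a block gave 8439 genes in PC3, 3777 in LNCaP, 5466 for the difference and 1626 in both lines, all within 1.5 times. With the block the spliceosome list in LNCaP did not pass (adjusted p = 0.0513), nor did the differences of FAS (0.0558), KLK2 (0.0600) and MDM4 (0.0521) or the LNCaP changes of CDH15, FCGBP and LINC01547 (0.0653 to 0.0796), while MDM2 in PC3, the difference of CPA4 and the cell cycle inhibitors and cyclins in LNCaP passed (0.0351 to 0.0446). Same-numbered libraries did not deviate together within a line (r = -0.0035 in PC3 and 0.0121 in LNCaP across genes), so the numbers were not taken to pair the samples. On the recovered reads, with 100% of values whole, edgeR called 9317 genes in PC3, 6305 in LNCaP and 6604 for the difference, and DESeq2 7125, 3866 and 4712. Reversed results were NDRG1 in PC3 (main -0.14, not past the test, 0.165 under quantile normalization, and past the test as a fall with upper-quartile scaling, DESeq2 or without either LNCaP control), the cytosolic ribosomal protein genes under quantile normalization (0.090 in PC3, 0.043 in LNCaP) and the direction of the mesenchymal markers in PC3 under fry (mean -0.072). Their cause was not tested. For the named genes, 5404 further comparisons kept their side of the threshold without a reversal, 260 lost the call and 63 gained one. Those kept include sign changes where neither value passed, and those lost include losses under the 2-fold minimum. For the lists the numbers kept, lost and gained were 1683, 79 and 55. With an estimated correlation all 9 lists of PC3, 14 of LNCaP and 16 of the difference lost their call. Since no list passed in any contrast, that version could not tell lists that moved from lists that did not. Depth limits genes with few reads, whose values depend most on the pseudocount. For gene lists the 2-fold minimum was not run.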

Other observations

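Long non-coding RNAs had 170 rises and 70 falls among 3018 tested in LNCaP, and 380 and 462 in PC3. They took 2.55% and 1.98% of the reads in LNCaP control replicates 1 and 2, and 2.61% and 2.57% in treated LNCaP. Control replicate 1 thus lay near the treated libraries, and the excess of rises may rest on control replicate 2. Classes were not counted under other scalings, which moved the share of rises over all LNCaP calls from 36.8% up to 58.3%. Protein-coding genes had 1345 rises and 2626 falls among 14370 in LNCaP, and 3205 and 4158 in PC3. Protein-coding genes took 91.1% and 91.05% of the reads in the PC3 controls and 88.3% and 88.5% in treated PC3.

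Several of the 28 gene lists did not pass camera. The counts give rises and then falls among the genes tested, each with its camera adjusted p, and were the same adjusted over the list alone unless given. In PC3 they were, for PRMT5 and its complexes 4 and 1 of 10 (adjusted p = 0.174), other arginine methyltransferases 1 and 5 of 8 (adjusted p = 0.105), p53 targets 8 and 13 of 29 (adjusted p = 0.294, 9 and 15 adjusted over the list alone) and androgen receptor targets 10 and 8 of 28 (adjusted p = 0.361, 11 and 8 adjusted over the list alone). The counts of chromatin and cell type genes were, for replication-dependent histones 5 and 7 of 23 (adjusted p = 0.964), epithelial markers 2 and 9 of 14 (adjusted p = 0.0783), mesenchymal markers 6 and 6 of 21 (adjusted p = 0.964) and neuroendocrine and neuronal genes 1 and 1 of 12 (adjusted p = 0.757, 0 and 1 adjusted over the list alone). Metabolic, apoptosis and translation genes counted, for glycolysis and hypoxia genes 8 and 8 of 27 (adjusted p = 0.325, 9 and 8 adjusted over the list alone), apoptosis regulators 0 and 12 of 24 (adjusted p = 0.0783), cytosolic ribosomal protein genes 1 and 15 of 40 (adjusted p = 0.0783) and mitochondrially encoded mRNAs 2 and 4 of 13 (adjusted p = 0.344). Early response, stress and line marker genes counted, for immediate early genes 4 and 6 of 16 (adjusted p = 0.707), heat shock genes 7 and 2 of 12 (adjusted p = 0.0783), luminal markers 5 and 4 of 15 (adjusted p = 0.593) and PC3-type markers 2 and 5 of 17 (adjusted p = 0.227). Markers of other cell types counted, for fibroblast markers 3 and 0 of 7 (adjusted p = 0.117) and blood and endothelial cell markers 2 and 1 of 4 (adjusted p = 0.660).

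In LNCaP the counts were, for PRMT5 and its complexes 0 and 0 of 10 (adjusted p = 0.687), other arginine methyltransferases 0 and 2 of 8 (adjusted p = 0.337), double-strand break repair genes 1 and 8 of 30 (adjusted p = 0.0976) and cholesterol synthesis genes 3 and 4 of 24 (adjusted p = 0.903, 4 and 5 adjusted over the list alone). Cell type and apoptosis genes counted there, for epithelial markers 3 and 4 of 14 (adjusted p = 0.669, 3 and 5 adjusted over the list alone), mesenchymal markers 3 and 2 of 21 (adjusted p = 0.511, 3 and 3 adjusted over the list alone), neuroendocrine and neuronal genes 0 and 2 of 12 (adjusted p = 0.389) and apoptosis regulators 4 and 4 of 24 (adjusted p = 0.763, 4 and 5 adjusted over the list alone). Cycle, stress and line marker genes counted, for cell cycle inhibitors and cyclins 4 and 9 of 22 (adjusted p = 0.0515, 4 and 11 adjusted over the list alone), immediate early genes 2 and 3 of 16 (adjusted p = 0.541, 3 and 3 adjusted over the list alone), heat shock genes 0 and 3 of 12 (adjusted p = 0.461) and PC3-type markers 5 and 4 of 17 (adjusted p = 0.185). Markers of other cell types counted in LNCaP, for fibroblast markers 0 and 0 of 7 (adjusted p = 0.647) and blood and endothelial cell markers 0 and 0 of 4 (adjusted p = 0.704).

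For the difference of responses, as genes with the more positive change in LNCaP and in PC3, the counts were, for PRMT5 and its complexes 1 and 3 of 10 (adjusted p = 0.340), other arginine methyltransferases 3 and 0 of 8 (adjusted p = 0.341), epithelial markers 6 and 2 of 14 (adjusted p = 0.273) and mesenchymal markers 7 and 4 of 21 (adjusted p = 0.601, 7 and 5 adjusted over the list alone). Neuronal, apoptosis, cycle and ribosomal genes counted, for neuroendocrine and neuronal genes 0 and 2 of 12 (adjusted p = 0.2504, 0 and 1 adjusted over the list alone), apoptosis regulators 8 and 0 of 24 (adjusted p = 0.0655, 9 and 0 adjusted over the list alone), cell cycle inhibitors and cyclins 6 and 7 of 22 (adjusted p = 0.979) and cytosolic ribosomal protein genes 3 and 0 of 40 (adjusted p = 0.865, 2 and 0 adjusted over the list alone). Early response genes and markers of other cell types counted, for immediate early genes 5 and 1 of 16 (adjusted p = 0.256, 7 and 1 adjusted over the list alone), fibroblast markers 0 and 2 of 7 (adjusted p = 0.256) and blood and endothelial cell markers 1 and 2 of 4 (adjusted p = 0.865). In PC3 the mesenchymal markers and histones had a mean below 0 (-0.07 and -0.02) while camera pointed up, and the immediate early genes a mean of 0.04 while camera pointed down. Fry pointed down for the neuroendocrine and neuronal genes, whose mean was 0.18. In LNCaP the cholesterol synthesis genes had a mean of -0.03 and a median of 0.03, the apoptosis regulators 0.02 and -0.01, and the fibroblast markers 0.02 and -0.13. For the difference, the integrated stress response had a mean of 0.01 and a median of -0.09, and the cell cycle inhibitors and cyclins -0.02 and 0.01. Medians were 0 for the androgen receptor targets and luminal markers in PC3 and for the mesenchymal markers in LNCaP.

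Some of these lists passed camera, at the preset correlation, under another setting. In PC3 the heat shock genes passed with upper-quartile scaling (mean 0.26, adjusted p = 0.0152), quantile normalization (0.325, adjusted p = 0.00135), the total without 7SL, 7SK and mitochondrial RNA (0.33, adjusted p = 0.00649), DESeq2 (adjusted p = 0.0282), no filter (adjusted p = 0.0318), only the 4 libraries compared (adjusted p = 0.0468) and without either LNCaP control. Glycolysis and hypoxia genes passed there as a rise under quantile normalization (mean 0.225, adjusted p = 0.00187) and with that total (0.20, adjusted p = 0.0160), against a mean of 0.07. The ribosomal protein genes passed as a fall with DESeq2 (adjusted p = 0.0498), no filter (adjusted p = 5.05e-04), only the 4 libraries compared (adjusted p = 0.0144) and without either LNCaP control. With no filter the epithelial markers, apoptosis regulators, other arginine methyltransferases and fibroblast markers also passed in PC3 (adjusted p from 0.00216 to 0.0205), as did the epithelial and PC3-type markers with DESeq2 (adjusted p = 0.00588 and 2.16e-09) and the apoptosis regulators without treated PC3 replicate 1. In LNCaP the double-strand break repair genes passed with no filter (adjusted p = 0.00488), the cell cycle inhibitors and cyclins with no filter (adjusted p = 0.00401), with edgeR (adjusted p = 0.0394) and without LNCaP control replicate 1 or either PC3 control, and the heat shock genes without LNCaP control replicate 1. The difference of the apoptosis regulators passed with no filter, edgeR, quantile normalization and upper-quartile scaling (adjusted p from 0.00962 to 0.0455) and without LNCaP control replicate 2 or treated PC3 replicate 1, and that of the ribosomal protein genes without LNCaP control replicate 2. Fry, which does not compare a list with other genes, called 20 of the 28 lists in PC3, 14 in LNCaP and 20 for the difference.

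One hypothesis, written before its test was run, was that genes with many exons would fall, since PRMT5 modifies splicing proteins. Exon number was counted as the separate exon blocks of a gene, merged over all its annotated transcripts. It also reflects how many transcripts are annotated and is not the number of splicing events per transcript. Across 14370 protein-coding genes, Spearman's rho between exon number and log2 change at equal expression and exonic length was 0.0804 in PC3 and 0.0402 in LNCaP, in each line opposite to the predicted sign. These tests were run across genes, which are not independent replicates, and neither rho was under the predicted bound of -0.1. The genes were also put in 4 groups from the fewest exons to the most, without adjustment for expression or length. The share called as falling in LNCaP was 14.9%, 17.1%, 19.5% and 21.6%, and the share called as rising 7.60%, 8.63%, 9.38% and 11.8%. In PC3 the shares falling were 31.9%, 29.8%, 27.3% and 26.7%, and those rising 17.5%, 22.4%, 23.9% and 25.4%.

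Another, also written before its test, was that the inhibitor makes the lines more alike. The difference between the lines in replicate 1 of the controls had a Spearman rho of -0.208 with the difference of responses computed with replicate 2 of the controls, so that no library was shared, and -0.200 with the numbers exchanged. The slope was -0.08, and the SD over genes of the difference between the lines was 2.40 in the controls and 2.30 in the treated cells. Among 11245 genes with a mean of at least 100 the first rho was -0.294. These values have the sign of a small convergence and lie under the predicted bound of -0.1. The 2 controls of a line may come from the same culture, however. A deviation common to both would give a negative rho by itself, so the test cannot tell it from convergence. Convergence was not tested for single gene lists.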
